A study of Mus musculus with 12 samples.

How the data were processed

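The series holds 12 ATAC-seq libraries of CD15+ cells from the dorsal telencephalon of CD1 mouse embryos at E12.5, in 4 sorted groups of 3 libraries. Groups were taken from the sample labels: double-negative, Ascl1-single (GFP+), Neurog2-single (mCherry+) and double-positive cells, with replicate numbers 2, 3 and 4 in each. The series design takes all groups from tissue with both reporter alleles, while the genotype label of each sample names only the alleles its gate shows, and the groups are read here as gates of one genotype. Per the labels, reads were placed on mm10, and the labels' tools are FastQC, BWA, bedtools and HOMER, without versions or roles. The program that called the regions is not named in these sources.

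Each library has one deposited list of accessible regions (hotspots) with a score per region, called at a false discovery rate of 1%, per the file names. The score column of the deposited lists carries no stated scale and was used only to shorten lists. Each group has one deposited footprint list, called with Wellington on the merged reads of its libraries at a false discovery rate of 1% per the file names, whose score is more negative for a stronger footprint and stops at -1000. Each group also has a deposited HOMER table of 319 known motifs. Per the file headers it gives the p-value and the Benjamini q-value of enrichment of each motif. It gives the natural log of the p-value, per the file headers. The authors also list the count of target sequences with the motif and an estimated count (weighted, not whole) of background sequences with it, per the file headers. The authors give the share of target and background sequences with the motif in percent, per the file headers. Target sequences numbered 978, 1473, 1761 and 2166 in double-negative, Ascl1-single, Neurog2-single and double-positive cells, within 1 of the footprint counts, and background sequences 39708, 38164, 38170 and 39059. How the background was chosen is not stated. None of the deposited files holds reads or coverage, so the depth of the libraries is unknown, and a region absent from a list may have fallen short of the caller's threshold.

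Tests, gene lists, naming rules and most alternatives were fixed before the data were examined. Coordinates are given on mm10, counted from 1. Genes came from a RefSeq table of the same assembly (GRCm38) with 21883 protein-coding genes, which gives gene spans without strand. The planned assignment to the nearest transcription start site was therefore replaced by the gene span nearest to the midpoint of a region, at most 100 kb away, and the planned promoter alternative by 1 kb on both sides of either gene end. Counts of sequence words in hotspots were not run, since no genome sequence was used here. Hotspots on the mitochondrial chromosome (13 over all libraries) were left out.

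Hotspot number and covered bases were compared by two-sided exact permutation tests, over 15400 partitions of the libraries for the 4 groups and 924 splits for the 2 reporter contrasts. Pairs of groups were not tested, as 3 libraries against 3 allow no p below 0.1. Similarity was the Jaccard index of covered bases, and its mean within minus between groups was tested one-sided over the same partitions. Hotspots of all libraries were merged into 586206 regions on chromosomes 1 to 19, X and Y, of which 422572 were called in 1 library and 24560 in all 12. A region counted as called with 1 bp of overlap, and 73.9% of regions had a gene within 100 kb. Regions called in 2 to 10 libraries were tested with Fisher's exact test and Benjamini-Hochberg adjustment.

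For genes, the covered bases of the regions nearest to each gene were summed and divided by the Mb covered in the library. Genes covered in at least 3 libraries (19622) were tested on log2(value + 10) with limma (lmFit and eBayes with trend) in one 4-group fit with 8 residual and 7.58 prior degrees of freedom. The contrasts were mCherry+ against mCherry−, GFP+ against GFP−, their interaction and the 6 pairs of groups, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The 17 fixed lists hold 333 genes, of which 324 were tested: radial glia, intermediate progenitor, glutamatergic, gabaergic, pan-neuronal, astrocyte, oligodendrocyte, Notch pathway, cortical layer, cell cycle, Cajal-Retzius, microglial, endothelial, erythroid, meningeal, choroid plexus and hem, and housekeeping genes. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it and with fry, and 40 of 153 tests passed in the first form. Some lists differ in sign between measures by mCherry: the meningeal list leans up in camera while its mean is slightly negative.

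Genes are named by a fixed rule: 28 core genes whatever their result, the 10 largest changes in each direction past the threshold by mCherry, by GFP and between double-positive and double-negative cells, up to 5 per direction in other contrasts, and up to 4 members per list. Where fewer than 5 passed, the smallest unadjusted p-values are given without a claim of change. For regions, the 5 with the most covered bases per set are named, and for motifs the 10 with the lowest p-value and a fixed set.

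Footprints counted as shared when at least 50% of the shorter one overlapped, with exact Clopper-Pearson 95% intervals. The motif tables were copied and not tested between groups. The region step was tested on 5250 simulated regions, where it recovered 100% of the planted exclusive regions and passed 7 checks. These were planted in every library of one side and in none of the other. Their recovery thus checks the counting only, and not how the step behaves where calls drop out. The limma step was tested on simulated values for all 19622 genes with 200 changed: by mCherry it recovered 78% of genes with a log2 change of 1 and 99% of those with 2, with 3.80% false calls, and between double-positive and double-negative cells 34% and 90%, with 3.88%. With no change simulated it called 0 genes, at limma's adjusted threshold.

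Alternatives covered the libraries (each left out in turn, or a block by replicate number), list length, chromosomes, the overlap and merging of regions, 500 bp bins, pseudocounts of 1 and 50, filters, scaling by quantile normalization, counting called regions instead of bases, the distance of genes, array weights, and stricter footprint lists. Added after seeing the data were leaving out both longest lists, the gene end window, removal of a gene density trend, list enrichment among regions, similarity by reporter, a look at gene families outside the lists, splits of group regions at equal list lengths and over all choices of 3 libraries, and footprint lists of equal length. Labels do not say that a replicate number marks a shared sort. Same-numbered libraries correlated above 0.1 in all 3 pairs only between double-positive and Neurog2-single cells (0.145, 0.222 and 0.135) and between double-negative and Neurog2-single cells (0.118, 0.185 and 0.177), and a block by number was read as pairing there alone. Computation used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.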

Results

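Open chromatin was profiled by ATAC-seq in neural progenitors of the dorsal telencephalon of CD1 mouse embryos at E12.5. The progenitors carried the surface epitope CD15 and were sorted from embryos with reporter alleles at 2 proneural genes, mCherry at Neurog2 and GFP at Ascl1. This gave 4 groups of 3 libraries each, made from 50000 cells: double-negative cells, Ascl1-single cells (GFP alone), Neurog2-single cells (mCherry alone) and double-positive cells. The labels number the libraries of each group 2, 3 and 4. The series asks how progenitors that express both proneural factors differ from those with one or none. The deposited lists give the accessible regions (hotspots) of each library, from 81123 in double-positive replicate 2 to 187146 in Neurog2-single replicate 3. The sequencing depth behind them is not in the files, and p-values here measure only the spread between libraries, since the labels do not say that the libraries come from separate animals.

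To see whether the reporters mark a change in the extent of open chromatin, the lists were compared in length. Double-negative libraries held 138532 ± 33091 hotspots (mean ± SD, n = 3), Ascl1-single libraries 101396 ± 11656, Neurog2-single libraries 127757 ± 51574 and double-positive libraries 94399 ± 12268. They covered 52.8 ± 5.74, 45.4 ± 5.84, 47.3 ± 11.4 and 44.0 ± 6.30 Mb of sequence. The 4 groups did not differ in hotspot number beyond the spread between libraries (two-sided exact permutation p = 0.298 over 15400 partitions). The mean of the 6 mCherry+ libraries differed from that of the 6 mCherry− libraries by -8886 (exact permutation p = 0.604). The corresponding GFP difference was -35247 (exact permutation p = 0.0563), and -3.45 and -5.33 Mb of covered sequence separated the sides of the mCherry and GFP contrasts (exact permutation p = 0.431 and 0.229). Leaving out a single library brought the GFP difference in hotspot number past the threshold in 3 cases, with exact permutation p = 0.0455 without double-negative replicate 4, 0.0152 without Neurog2-single replicate 2 and 0.0281 without Neurog2-single replicate 4.

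On average, libraries of one sorted population shared slightly more accessible sequence than libraries of different populations. The mean Jaccard index of covered bases was 0.370 within groups and 0.351 between groups, a difference of 0.0194 (one-sided exact permutation p = 0.00266). Double-positive libraries were the most alike, at 0.434 ± 0.0289 (SD over 3 pairs), and double-negative libraries the least, at 0.312 ± 0.0355. This order is on the full lists, which were shortest on average in double-positive and longest in double-negative cells. Double-negative replicates 2 and 3, with 131500 and 174574 hotspots, had 0.271 with each other. Double-negative replicate 4, with 109522, had 0.432 and 0.449 with Ascl1-single replicates 3 and 4. Ascl1-single pairs averaged 0.401 ± 0.0424 and Neurog2-single pairs 0.334 ± 0.0489. Across groups, Neurog2-single and double-positive libraries shared most (0.382 ± 0.0514 over 9 pairs), followed by Ascl1-single and double-positive libraries (0.380 ± 0.0370), while double-negative and Neurog2-single libraries shared least (0.312 ± 0.0473). Pairs of double-negative libraries lay below their pairs with Ascl1-single (0.350 ± 0.0555) and double-positive libraries (0.331 ± 0.0433), and Neurog2-single pairs below theirs with double-positive and Ascl1-single libraries (0.351 ± 0.0465). Without Neurog2-single replicate 3, the longest list, the remaining Neurog2-single pair had 0.3875. The difference was no longer past the threshold without any one of 5 of the 6 GFP+ libraries: it was 0.0119 (p = 0.109) without Ascl1-single replicate 2, 0.0159 (p = 0.0585) without Ascl1-single replicate 3, and 0.00897 (p = 0.142), 0.00765 (p = 0.190) and 0.0114 (p = 0.107) without double-positive replicates 2, 3 and 4, all by the same exact permutation test. Sorting the libraries by mCherry gave a difference of 0.0240 (exact permutation p = 0.00216) and sorting them by GFP one of 0.0024 (p = 0.253), which passed only without Neurog2-single replicate 4 (0.0155, exact permutation p = 0.0303).

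**Figure D1:**
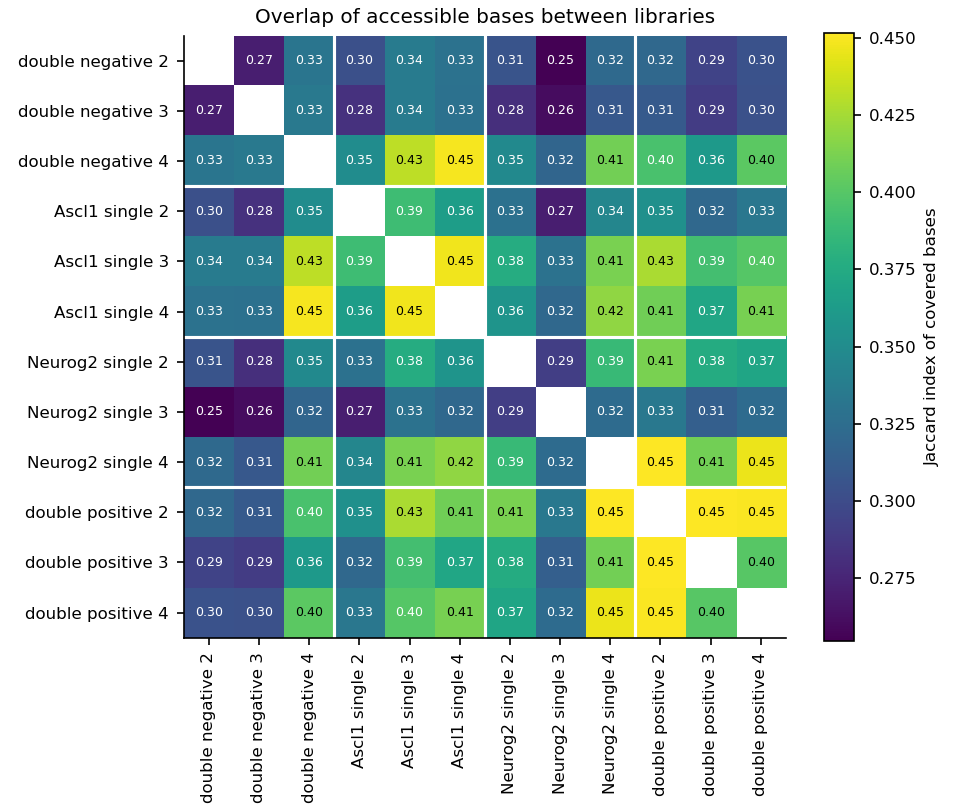
Jaccard index of the covered bases for every pair of the 12 libraries, ordered double-negative, Ascl1-single, Neurog2-single and double-positive, with replicates 2, 3 and 4 in each group and white lines between groups. Pairs of double-positive libraries average 0.434 and pairs of double-negative libraries 0.312.

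Regions that separate cells with and without the Neurog2 reporter were sought in the 586206 merged regions of all lists (mm10). Of these, 541 were called in all 6 mCherry+ libraries and in none of the 6 mCherry− libraries, and 59 showed the opposite pattern. No single region passed Fisher's exact test after Benjamini-Hochberg adjustment over 132798 regions, where 2315 had an unadjusted p below 0.05. With 6 libraries on each side, the smallest p this test can give passes only if far more regions separate the sides fully. The outcome was thus nearly fixed by the design and does not speak against single regions. The mCherry+ regions with the most covered bases lay on chromosome 11 at 45591717–45593742 (259.2 kb from Clint1, measured here and below from the midpoint of the region), on chromosome 12 at 6637683–6639736 (1263.0 kb from Klhl29) and on chromosome 5 at 17499661–17501583 (19.7 kb from Speer4f1). The next were on chromosome 9 at 94189511–94191474 (327.4 kb from Dipk2a) and inside Arl15 on chromosome 13 at 114129900–114131576. Among the mCherry− regions, the top 5 lay inside Mrpl58 (chromosome 11, 115408928–115410694), 177.5 kb from Bcl2l11 (chromosome 2, 128339143–128340921), 4.8 kb from Gsx2 (chromosome 5, 75070094–75071443), 54.3 kb from Nxnl2 (chromosome 13, 51228920–51230101) and 4.6 kb from Zic4 (chromosome 9, 91393267–91394713). Ptprd, Cnr1 and Ptprk were each nearest to 3 mCherry+ regions. Neuronal and cortical genes with an mCherry+ region included Unc5d, with 2, and Plxna4, Nrp1, Elavl2, Syt1, Nrxn1, Reln, Foxp2 and Satb2, while Cxcr4 and Ncam1 had an mCherry− region. The mCherry+ regions were wider than the 7445 regions called in any 6 libraries (median 763 against 569 bp), and 46.6% of them lay inside a gene, against 44.6%. They lay in surroundings with a median of 4 protein-coding genes within 500 kb, against 7 for the mCherry− regions and 6 for the background. No fixed gene list was enriched near them, with glutamatergic genes at 4 of 541 regions against 18 of 7445 in the background (Fisher's exact p = 0.0373, adjusted p = 0.633).

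**Figure D2:**
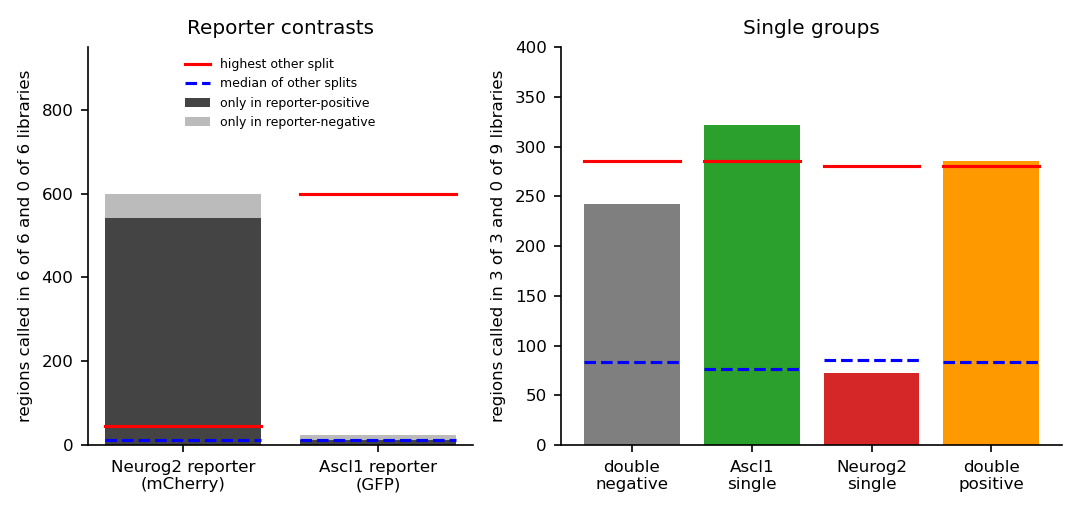
Number of merged regions called in every library of one side and in no library of the other. Left, the mCherry (Neurog2) and GFP (Ascl1) reporters, stacked as reporter-positive (dark) and reporter-negative (light) regions; right, the 4 sorted groups. The red line marks the highest and the blue dashed line the median count among other splits of the 12 libraries, and the 600 mCherry regions stand above all of them.

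The Ascl1 reporter separated few regions. Only 12 regions were called in all 6 GFP+ libraries alone and 11 in all 6 GFP− libraries alone, and none passed Fisher's exact test after adjustment, where 264 had an unadjusted p below 0.05. As for mCherry, this test could hardly pass any region with 6 libraries on each side, so its outcome tells little. These few GFP+ regions included one 159.6 kb from Got2 (chromosome 8, 96047446–96048584) and others inside Myo10, Lama2, Gm19345 and Atp2b1. GFP− regions included those in Sipa1l3, Zfp296, Brsk1 and Rasef and one 37.7 kb from Prl2c3. From the fixed gene lists, Gap43 alone had a GFP+ region.

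Regions private to one population were counted in the same way. There were 322 regions called in all 3 Ascl1-single libraries and in no other, 285 for double-positive, 242 for double-negative and 72 for Neurog2-single cells, although 38402 to 41156 regions were called in all 3 libraries of each group. This order was not stable: double-positive cells had more than Ascl1-single cells with 50% of the region covered (492 against 475) and at equal list lengths (433 against 401, with 78 in double-negative and 37 in Neurog2-single cells). The double-positive regions included one near Ascl1 itself, others near Pbx1, Elavl2, Foxp2, Rorb, Ebf2 and Plk1, and 3 with Ptprd as the nearest gene. Their regions with the most covered bases lay 58.9 kb from Lrrn1 (chromosome 6, 107470165–107471567), 30.2 kb from Cbln4 (chromosome 2, 172005651–172006614), 16.2 kb from Mturn, 3.0 kb from Cldnd1 and inside Stard13. Ascl1-single regions lay near Otx2, Dlx6, Meis2, Nfia and Foxp2, which had 2, and of the top 5, one lay 37.4 kb from Siah2, one 4.0 kb from Cd83 and 3 had no gene within 100 kb. Double-negative regions lay near the oligodendrocyte genes Sox10 and Gpr17 and near Bcl11b and Cux1, and of the top 5, one lay inside Ush2a, one 45.4 kb from Edn2, one 0.2 kb from Mobp and 2 had no gene within 100 kb. The top Neurog2-single regions lay inside Drd3, Grip1 and Gjb6, 35.0 kb from Mup18 and 86.0 kb from LOC115490339. Over 136 tests of gene lists near these and the reporter-specific regions the smallest adjusted Fisher's exact p was 0.314, for oligodendrocyte genes at 2 double-negative regions.

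Neurod1 and Nhlh1, genes of the neuronal differentiation cascade, had more covered bases in cells with the Neurog2 reporter, while Gsx2 and Wnt4 had fewer. The calls of Neurod1, Nhlh1 and Gsx2 did not hold with regions counted instead of bases. Accessibility per gene was taken as hotspot-covered bases in the regions nearest to it, per Mb covered in the library, and tested with limma for 19622 genes on a log2(value + 10) scale, which understates the change of genes with low values. Of these, 216 were higher and 480 lower in mCherry+ cells at an adjusted p below 0.05 (3812 at an unadjusted p below 0.05). With quantile normalization, which shifted the median over all genes by 0.09, the split was 222 higher and 253 lower. Neurod1 rose from 48.2 ± 3.99 in double-negative and 90.8 ± 12.6 in Ascl1-single libraries to 111 ± 11.99 in Neurog2-single and 147 ± 18.0 in double-positive libraries (SD, n = 3; log2 fold change 0.85, SE 0.12, limma adjusted p = 0.00391). Nhlh1 rose by 0.84 on the log2 scale (SE 0.13, limma adjusted p = 0.00752), with 64.2 ± 8.28, 72.6 ± 10.8, 118 ± 28.8 and 145 ± 13.3 in the 4 groups in the same order. Further up the scale, Neurod4 (1.13, limma adjusted p = 0.0413), Neurog3 (1.17, adjusted p = 0.0225) and Dcx (0.75, adjusted p = 0.0482) were also higher. The other genes with the largest increases were Serpinb2 (1.39), Reg3b (1.38), Clca3a2 (1.24), Aldob (1.22), Ermard (1.17), Pax4 (1.16) and Zc2hc1b (1.12), with limma adjusted p between 0.00518 and 0.0132, and Them5, which was listed at 0 in every mCherry− library and at 13.9 ± 3.81 and 22.0 ± 11.8 in Neurog2-single and double-positive libraries. Ermard had the highest values among them, 45.9 ± 18.3, 40.8 ± 10.8, 116 ± 10.5 and 99.5 ± 23.2.

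In the other direction, Gsx2, which specifies ventral progenitors, fell by 1.70 on the log2 scale (SE 0.22, limma adjusted p = 0.00391), from 53.4 ± 7.62 in double-negative and 91.6 ± 16.0 in Ascl1-single cells to 15.5 ± 8.33 in Neurog2-single and 16.5 ± 11.1 in double-positive cells. Wnt4 fell by 1.71 (SE 0.23, limma adjusted p = 0.00391), with 62.7 ± 22.2, 34.8 ± 13.4, 8.94 ± 7.19 and 5.63 ± 1.20 in the same order of groups. Dlx2 was lower by a log2 fold change of -0.75 (SE 0.20, limma adjusted p = 0.0476), a call lost in 11 of the 12 fits without one library. The remaining large decreases were in Cdc42ep1 (-1.63), Scube1 (-1.55), Foxl1 (-1.51), Nbl1 (-1.46), Gpr179 (-1.43), Ripor3 (-1.40), Ehbp1l1 (-1.38) and Fam83h (-1.35), with limma adjusted p between 0.00391 and 0.0494. Gsx2 itself lies on chromosome 5 at 75075601–75077893, near one of the mCherry− regions.

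Chromatin at both reporter genes differed little with the reporters. Neurog2 (chromosome 3, 127632733–127635636) had 175 ± 31.4, 205 ± 12.1, 185 ± 6.597 and 194 ± 19.7 covered bases per Mb in double-negative, Ascl1-single, Neurog2-single and double-positive libraries, a log2 difference of 0.01 by mCherry (limma adjusted p = 0.987). Ascl1 (chromosome 10, 87490819–87493660) had 185 ± 31.4, 205 ± 23.0, 165 ± 47.5 and 181 ± 11.7, a log2 difference of -0.17 (limma adjusted p = 0.526). Eomes missed the threshold by mCherry with 0.57 (adjusted p = 0.05002). The other core genes past no threshold were Gad2 (0.45), Fut4 (0.51, an enzyme able to make the CD15 epitope), Tbr1 (0.29), Insm1 (0.22), Dll1 (0.21), Gadd45g (0.20), Foxg1 (0.20), Olig2 (0.16), Rnd2 (0.15), Hes6 (0.07), Lhx2 (0.01), Pax6 (-0.12), Neurog1 (-0.12), Hes5 (-0.14), Dll3 (-0.18), Emx1 (-0.31), Hes1 (-0.32), Sox2 (-0.41) and Dlx1 (-0.66), with limma adjusted p from 0.0757 to 0.976.

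**Figure D3:**
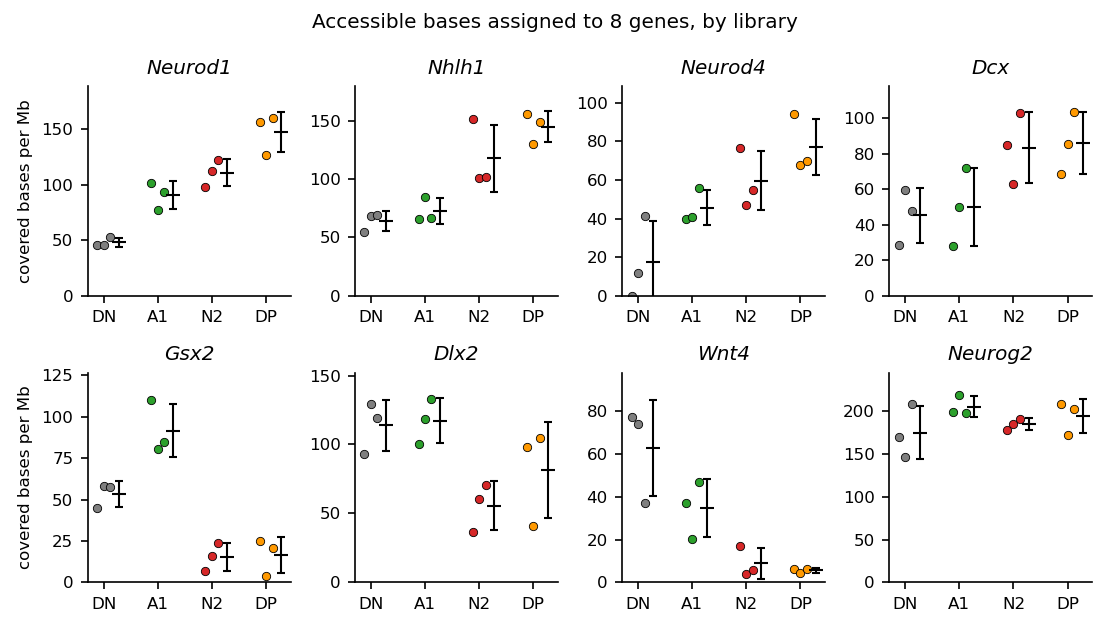
Hotspot-covered bases per Mb covered in the library, assigned to Neurod1, Nhlh1, Neurod4, Dcx, Gsx2, Dlx2, Wnt4 and Neurog2 in double-negative (DN), Ascl1-single (A1), Neurog2-single (N2) and double-positive (DP) cells; points are libraries and bars means ± SD (n = 3). Neurod1 goes from 48.2 in double-negative to 147 in double-positive cells and Wnt4 from 62.7 to 5.63, while Neurog2 stays between 175 and 205.

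The number of genes called by mCherry depended on single libraries, but most named calls did not. It was 249, 350 and 331 without Ascl1-single replicates 2, 3 and 4, 360 and 251 without double-positive replicates 2 and 3, 208 and 416 without double-negative replicates 2 and 3, and 323 and 325 without Neurog2-single replicates 3 and 4. Counted only within 1 kb of either gene end, 15 genes were higher and 14 lower, and with regions counted instead of bases 7 and 22. With gene ends, Neurod4 (-0.09) and Zc2hc1b changed sign, as Aldob (-0.21) did when counted over its gene body with 10 kb. Of the 24 named calls, 17 held without any one library, Neurod1, Nhlh1, Gsx2 and Wnt4 among them. With regions counted instead of bases, however, 19 of the 24 were lost, with limma adjusted p of 0.560 for Neurod1 and 0.322 for Nhlh1, and Gsx2 lost as well. With gene ends, 13 of the 17 that could be tested were lost, Wnt4 (adjusted p = 0.379) and Gsx2 (0.109) among them. Dcx was called only without Ascl1-single replicate 4 or double-negative replicate 3 (highest limma adjusted p 0.114), Dlx2 only without double-positive replicate 4 (0.0993) and Neurod4 only without double-positive replicate 4 or double-negative replicate 4 (0.0903). Ripor3 was lost in 9 of the 12 fits (adjusted p up to 0.117; kept without Ascl1-single replicate 3, double-positive replicate 4 or double-negative replicate 3). Fam83h was lost in 8 (up to 0.0955; kept without Ascl1-single replicate 3, double-positive replicate 4, double-negative replicate 4 or Neurog2-single replicate 2). Neurog3 was lost without Ascl1-single replicate 3 or double-negative replicate 2 (0.0565), and Gpr179 without Ascl1-single replicate 2 or double-negative replicate 2 (0.0531).

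Fixed gene lists were tested as well, where the camera calls all depend on a preset correlation between genes. Of 20 glutamatergic genes, 7 were higher and none lower by mCherry over all genes, and 9 adjusted over the list alone. Slc17a6 (log2 fold change 0.81, SE 0.12, limma adjusted p = 0.00700), Nhlh2 (0.999, SE 0.19, adjusted p = 0.0191) and Unc5d (0.49, adjusted p = 0.0415) joined Neurod1 and Nhlh1. Among intermediate progenitor genes 4 of 20 were higher (5 adjusted over the list alone), including Elavl4 (0.47), Abcd2 (0.61) and Slc16a2 (0.55), and among pan-neuronal genes 4 of 25 (5 over the list alone), including Elavl2 (0.60) and Gap43 (0.57). Camera placed the glutamatergic (adjusted p = 1.72e-07; adjusted p = 0.138 with an estimated correlation), pan-neuronal (3.16e-05; 0.0812 with an estimated correlation) and intermediate progenitor genes (2.45e-04; 0.270 with an estimated correlation) above other genes, and astrocyte genes below (0.0481; 0.355 with an estimated correlation). No list in any contrast passed with an estimated correlation. The astrocyte call was lost without any one of Ascl1-single replicates 3 (adjusted p = 0.0616) and 4 (0.231), double-positive replicates 2 (0.0543) and 3 (0.0661), double-negative replicates 3 (0.0616) and 4 (0.0857) and Neurog2-single replicate 2 (0.123).

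Single members of lists for other fates were lower in mCherry+ cells, while most of these lists as a whole did not pass camera (adjusted p = 0.0791 for gabaergic, 0.0656 for oligodendrocyte, 0.0642 for choroid plexus and hem, 0.514 for radial glia and 0.825 for Notch pathway genes). Gabaergic genes had 4 of 25 lower and none higher (5 lower and 1 higher adjusted over the list alone), Six3 (-0.89, limma adjusted p = 0.0232) and Sp9 (-0.74, adjusted p = 0.0386) beside Gsx2 and Dlx2. Oligodendrocyte genes had 3 of 15 lower (4 lower and 1 higher over the list alone), namely Olig1 (-1.19), Bcas1 (-0.93) and Sox8 (-0.91). Astrocyte genes had 2 of 15 lower (5 lower and 1 higher over the list alone), Id3 (-0.76) and Aldoc (-0.80). Notch pathway genes had 3 of 28 lower (4 lower and 1 higher over the list alone), Lfng (-0.73), Notch1 (-0.59) and Notch2 (-0.58), and radial glia genes 2 of 25 (2 over the list alone), Sox1 (-0.60) and Nes (-0.58). Choroid plexus and hem genes had 3 of 16 lower (6 lower and 1 higher over the list alone), Rspo1 (-0.82), Bmp7 (-0.72) and Otx2 (-0.71). Cajal-Retzius genes went both ways, with Nhlh2 and Ebf2 (0.57) higher and Lhx5 (-1.20) lower, and 4 higher and 1 lower over the list alone. Of the control and other cell type lists, meninges and pericyte genes had 3 lower (4 higher and 4 lower over the list alone), and one gene each was lower among cell cycle (Ccnd1, -0.55; 2 over the list alone), cortical layer (Bcl11b, -0.56; 2), erythroid (Rhd, -0.85; 2) and housekeeping genes (Actb, -0.69; 1). Microglial and endothelial genes had none over all genes, by limma. Of these 38 list members past the threshold, 11 held without any one library, Slc17a6, Nhlh2, Elavl2, Bcas1, Sox8, Id3, Lhx5 and Alx4 besides Neurod1, Nhlh1 and Gsx2.

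Cells with both reporters were set against cells with neither, which span the extremes of the sort. Here 149 genes were higher and 340 lower in double-positive cells by limma, or 105 higher and 141 lower with quantile normalization, which shifted the median of all genes by 0.134, and 139 and 151 at equal list lengths. Only 13 were higher and 1 lower within 1 kb of gene ends, and 2 higher and 24 lower with regions counted instead of bases. Neurod1 was again higher, by a log2 fold change of 1.43 (SE 0.16, limma adjusted p = 0.00401), and so were Neurod4 (1.95, SE 0.40, adjusted p = 0.0255), Nhlh1 (1.06, SE 0.18, adjusted p = 0.0165) and Gad2 (0.86, SE 0.19, adjusted p = 0.0312). Gad2 had 63.8 ± 11.6 covered bases per Mb in double-negative and 124 ± 19.1 in double-positive cells (SD, n = 3). The largest other increases were in Serpinb2 (1.69), Gm2956 (1.63), Krtap14 (1.47), Dennd11 (1.47) and Zc2hc1b (1.45), with limma adjusted p between 0.0166 and 0.0436. Gprc6a rose from 5.41 ± 1.55 to 34.8 ± 13.7 (limma adjusted p = 0.0182). Them5 and Olfr1056 were listed at 0 in all double-negative libraries and at 22.0 ± 11.8 and 18.0 ± 4.08 in double-positive ones. The calcium channel subunit gene Cacna2d4 fell by 2.24 on the log2 scale (SE 0.33, limma adjusted p = 0.00792), from 54.0 ± 14.1 to 3.59 ± 3.12, Wnt4 by 2.17 (SE 0.32) and Myo5b by 2.00 (SE 0.31, adjusted p = 0.00875), from 103 ± 6.75 to 19.95 ± 11.5. The other large decreases were in Tgm2 (-2.21), Foxl1 (-2.08), Scube3 (-1.98), Fam131c (-1.96), Adra2c (-1.95), Foxf1 (-1.92) and Afap1l2 (-1.90), with limma adjusted p between 0.00792 and 0.0354, and Gsx2 also fell by 1.36 (SE 0.32, adjusted p = 0.0373).

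The remaining core genes did not pass between double-positive and double-negative cells. The values nearest to the threshold were Dll1 (0.62, limma adjusted p = 0.0609), Foxg1 (0.65, adjusted p = 0.0640), Eomes (0.71, adjusted p = 0.0848) and Dcx (0.82, adjusted p = 0.122). Fut4 (0.60), Gadd45g (0.50), Tbr1 (0.48), Insm1 (0.46), Olig2 (0.46), Pax6 (0.18), Rnd2 (0.17), Lhx2 (0.16), Neurog2 (0.15), Neurog1 (0.15), Hes6 (0.10) and Dll3 (0.06) had positive log2 differences, Ascl1 (-0.02), Hes1 (-0.23), Sox2 (-0.33), Emx1 (-0.38), Dlx2 (-0.51) and Dlx1 (-0.64) negative ones, and Hes5 one of 0.00. Only 6 of the 23 named calls held without any one library, Neurod1, Cacna2d4, Wnt4, Foxl1, Myo5b and Adra2c, and the number of calls was 70 and 48 without double-positive replicates 2 and 3 and 36 and 143 without double-negative replicates 2 and 3. With regions counted instead of bases 18 of the 23 were lost, and with gene ends 14 of the 19 that could be tested. Over all genes, 4 of 20 glutamatergic genes were higher (10 adjusted over the list alone; Slc17a6 1.07), 3 of 20 intermediate progenitor genes (5; Elavl4 0.96, Slc16a2 0.86) and 3 of 25 pan-neuronal genes (8 higher and 1 lower; Elavl2 0.93, Gap43 0.72). Camera placed these 3 lists above other genes, with adjusted p of 1.19e-08, 3.72e-05 and 1.31e-05 (0.0973, 0.220 and 0.0658 with an estimated correlation). Lower were Sp9 (-1.27) among gabaergic genes, Sox8 (-1.30) and Bcas1 (-1.14) among oligodendrocyte genes, Egfl7 (-1.77), Eng (-1.45) and Flt1 (-0.95) among endothelial genes, Col1a1 (-1.26) and Pdgfrb (-1.04) among meningeal genes, Cux1 (-0.73) and Ccnd1 (-0.76). Of the 20 list members past the threshold, 2 held without any one library, Neurod1 and Elavl4.

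The Ascl1 reporter alone called no gene. Limma passed 0 of 19622 genes by GFP, where 1720 had an unadjusted p below 0.05, and 0 in the interaction that asks whether both reporters together differ from the sum of each (762 unadjusted). By GFP the smallest p-values belonged to Fbxo8 (0.63), Ostf1 (0.67), Neurod1 (0.58), Elavl4 (0.49) and Prdm8 (0.63) with positive log2 differences and to Prl4a1 (-1.05), Lyrm4 (-1.13), Fnbp1 (-1.05) and Spink5 (-1.18) with negative ones, at limma adjusted p of 0.230 to 0.247. Zfp296 was listed at 0 in every GFP+ library. All 28 core genes stayed below the threshold, Neurod4 with the largest difference (0.82, adjusted p = 0.447), then Foxg1 (0.45), Dll1 (0.41) and Gad2 (0.41), with Neurog2 at 0.15 and Ascl1 at 0.15. Adjusted over the list alone, 5 gabaergic genes were higher by GFP, Isl1, Arx (0.50), Gad2, Six3 (0.56) and Zeb2, and Sp9 (-0.53) was lower. Camera called 6 lists higher by GFP, glutamatergic (adjusted p = 6.15e-04), gabaergic (6.15e-04), radial glia (0.00474), intermediate progenitor (0.00818), pan-neuronal (0.0125) and cortical layer genes (0.0213), each with an adjusted p of 0.349 with an estimated correlation. With quantile normalization 5 of these 6 lists were not called, the exception being the gabaergic one. Leaving out single libraries moved the number of lists called between 3, without double-positive replicate 4, and 10, without double-positive replicate 3. In the interaction, Esp4 (1.74), Krt88 (1.60), Ucp1 (1.75) and Qrich2 (1.67) had the largest positive and Otx2 (-1.78), Icos (-1.54), Dgkz (-1.36), Camkmt (-0.97) and 6030498E09Rik (-1.73) the largest negative estimates among the smallest p-values, at limma adjusted p of 0.899 or more, beside Mboat7, listed at 0 outside double-negative cells.

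Double-positive cells were also set against each single-positive group. Between double-positive and Neurog2-single cells limma called 0 genes (1087 unadjusted), with Eif3e (0.76), Acyp2 (0.72), Ankrd1 (0.62), Atp6v0d2 (1.07) and Zfp658 (0.82) on the positive and Col26a1 (-1.11), 3830403N18Rik (-1.18), Ces2g (-1.30), Steap3 (-1.02) and Med13l (-0.73) on the negative side (adjusted p 0.643 to 0.667). Between double-positive and Ascl1-single cells 4 genes were higher and 17 lower, a number that ran from 0 within 1 kb of gene ends to 294 with array weights. Acyp2 (1.15, SE 0.19, limma adjusted p = 0.0279) and Plcxd2 (0.80, adjusted p = 0.0493) were higher, and Them5 and Olfr798 were listed at 0 in Ascl1-single cells. Among the lower genes, Otx2 fell from 201 ± 29.8 to 61.4 ± 21.1 covered bases per Mb (SD, n = 3; log2 fold change -1.60, SE 0.25, limma adjusted p = 0.0265), Six3 from 134 ± 35.6 to 39.0 ± 8.92 (-1.54, SE 0.27, adjusted p = 0.0442) and Gsx2 from 91.6 ± 16.0 to 16.5 ± 11.1 (-2.03, SE 0.32, adjusted p = 0.0265), beside Pdlim3 (-1.69) and Alpl (-1.57). Otx2 and Six3 were highest in Ascl1-single cells among the 4 groups, with 88.5 ± 36.9 and 53.5 ± 21.6 in double-negative and 96.3 ± 0.958 and 42.5 ± 12.3 in Neurog2-single cells. None of these named calls held without any one of Ascl1-single replicates 2, 3 and 4 or double-positive replicate 2, where 0 genes passed, and 1 passed without double-positive replicate 3. Conversely, 110 passed without double-positive replicate 4, 36 without double-negative replicate 2, 33 without Neurog2-single replicate 2 and 10 without Neurog2-single replicate 3.

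The 3 other pairs of groups were compared in the same way. Mrpl58 was the single gene called between Neurog2-single and Ascl1-single cells (28.8 ± 5.14 against 87.9 ± 6.86 covered bases per Mb; log2 fold change -1.34, SE 0.18, limma adjusted p = 0.0351; 1856 unadjusted), and its call was lost in 9 of 12 fits without one library (adjusted p up to 0.208). Between Neurog2-single and double-negative cells 2 genes were higher and 5 lower (2242 unadjusted). Reg3g rose from 18.2 ± 2.39 to 74.0 ± 4.80 (1.58, SE 0.18, limma adjusted p = 0.00544; 0.0754 without Neurog2-single replicate 4), and Neurod1 was higher by 1.05 (adjusted p = 0.0301; lost in 9 of 12 fits, up to 0.241). Wnt4 (-1.95), Lypd4 (-1.73) and Sf3a2 (-1.48) were lower, Oplah was listed at 0 in Neurog2-single cells, and Mboat7 was covered in double-negative libraries only, at 17.3 ± 5.80. None of the 7 calls held without any one library: Wnt4 and Lypd4 were lost in 10 of 12 fits, Sf3a2 in 9, Oplah in 7 and Mboat7 in 8 of 10 (limma adjusted p up to 0.343). Over those fits 0 to 13 genes passed. With the replicate number as a block 5 genes were higher and 15 lower, the 7 called genes, Fbxo48 and Gadd45a among them. Between Ascl1-single and double-negative cells limma called 0 genes (1408 unadjusted), and 1 without double-negative replicate 3. Stx3 (1.04), Fezf1 (1.29), Neurod1 (0.79), Otx2 (1.15) and Six3 (1.21) had the smallest p-values with a positive difference, and Prl4a1 (-1.39), Adam12 (-1.02), Adam8 (-1.45) and Gm826 (-1.42) with a negative one (limma adjusted p 0.286 to 0.512), beside Mboat7 (0.138), listed at 0 in Ascl1-single cells.

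Footprints, short protected stretches within open regions that the authors called on the merged libraries of each group, were most numerous in double-positive cells. There were 977 in double-negative, 1474 in Ascl1-single, 1760 in Neurog2-single and 2165 in double-positive cells, one list per group and so without replicate error. The depth of the merged reads is unknown, and its part in these counts was not tested. Of the double-positive footprints, 41.7% (95% Clopper-Pearson interval 39.6–43.8) overlapped none of another group, against 24.7% (22.0–27.5), 26.9% (24.6–29.2) and 29.9% (27.8–32.1) in the others. These shares rise with the length of the list: among the 977 strongest footprints of each group they were 37.7% in double-negative, 26.1% in Ascl1-single, 23.8% in Neurog2-single and 27.7% in double-positive cells. Intervals cover counting error only. Foxp2 had 3 footprints in double-positive cells and none elsewhere, and Ccna2 had 2, while Rorb had 3 in Neurog2-single and 2 in double-positive cells and Hey2 had 2 and 3. Scg3 had 2 in double-negative cells alone, and Tle4 had 4 there and 2 in each other group. Among footprints at the score limit of -1000, one on chromosome X at 143483040–143483060 near Pak3 was found in Neurog2-single cells only, while those near Rpusd4 (chromosome 9, 35305413–35305437) and Gtpbp4 (chromosome 13, 9011758–9011782) had partners in other groups. Others at this limit lay on chromosome 9 between 3002104 and 3024492, in every group and with no gene within 100 kb. No filter for stretches of unreliable mapping was applied here, so these scores are not read as binding.

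Motifs in the footprints were read from the authors' deposited tables, which hold 319 known motifs per group. Motifs with a q-value below 0.05 in the authors' deposited tables numbered 69 in double-negative, 70 in Ascl1-single, 88 in Neurog2-single and 100 in double-positive cells. By the authors' deposited table the leading motif was NFY in double-negative (natural log of p -45.3) and Ascl1-single cells (-79.0), KLF5 in Neurog2-single cells (-86.3) and NRF in double-positive cells (-95.8). The LIM homeodomain motif Lhx2 ranked 3 in double-positive cells, where the authors' deposited table gives it in 3.74% of sequences against 0.59% of the background. It had 2.76% (background 0.50%) in double-negative, 1.15% (0.39%) in Ascl1-single and 1.59% (0.47%) in Neurog2-single cells in the authors' deposited tables. Lhx3 (5.08%) and Lhx1 (3.88%) followed in double-positive cells in the same authors' deposited table, with NRF1, Elk4, Elk1, KLF5, NFY and Nkx6.1 making up its first 10. These motifs were not particular to double-positive cells: Lhx1, Lhx3 and Lhx2 ranked 3, 6 and 9 in double-negative cells. Their shares there were 5.66, 4.37 and 5.52 times the background, against 5.62, 4.50 and 6.34 times in double-positive cells. NFY was found in 3.68%, 4.48%, 4.49% and 3.56% of sequences of double-negative, Ascl1-single, Neurog2-single and double-positive cells in the authors' deposited tables, KLF5 in 6.86%, 8.34%, 9.20% and 7.53%, and NRF in 3.28%, 3.46%, 4.09% and 4.71%. The Ascl1 motif passed in no authors' deposited table (0.82%, 0.27%, 0.34% and 0.65%, with q-values of 0.429, 1, 1 and 0.624). NeuroD1 reached 0.92% (q = 0.0035) in double-negative and 0.55% (q = 0.0465) in double-positive cells, and 0.34% and 0.23% without passing in Ascl1-single and Neurog2-single cells, again in the authors' deposited tables. Eomes (1.20%, q = 0.0234) and Sox3 (1.48%, q = 0.0208) passed in the authors' deposited table of double-positive cells, and Olig2 (q = 0.0265) in that of double-negative cells. Differences between groups were not tested, since each has one list.

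**Figure D4:**
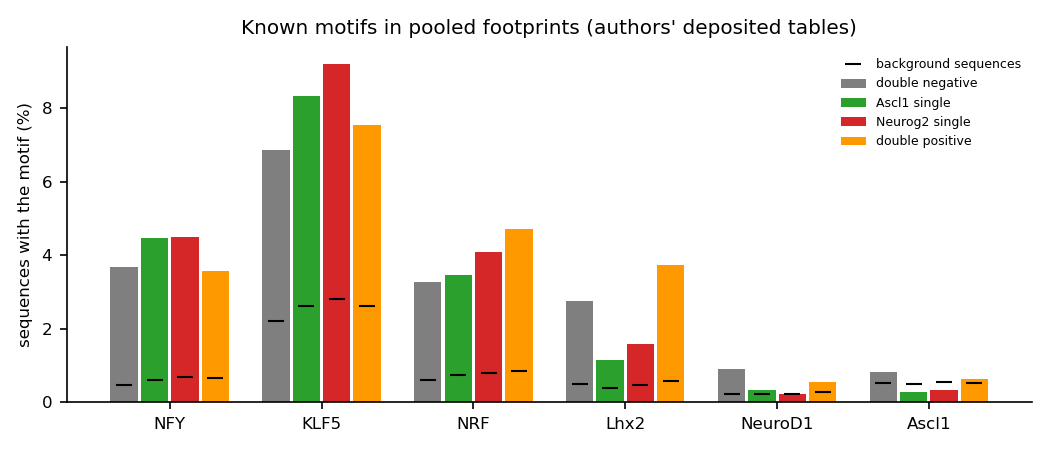
Percent of footprint sequences holding the NFY, KLF5, NRF, Lhx2, NeuroD1 and Ascl1 motifs in the 4 groups, from the authors' deposited tables; bars are footprint sequences and black marks background sequences. Lhx2 stands at 3.74% in double-positive, 2.76% in double-negative and 1.15% in Ascl1-single cells.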

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

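The tests of the 3 patterns weighed here, and the counts of genes and regions over other splits of the libraries, were chosen only after the results were seen; the splits of gene lists were planned before them.

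Otx2 (chromosome 14, 48656781–48667644) stood out because its response to both reporters together differed from the sum of each: its interaction estimate was -1.78 on the log2 scale. Its adjusted p was 0.00258 over the choroid plexus and hem list alone but 0.99989 over all genes (limma). The estimate follows from the high value in Ascl1-single cells, 201 ± 29.8 covered bases per Mb, against 88.5 ± 36.9, 96.3 ± 0.958 and 61.4 ± 21.1 in double-negative, Neurog2-single and double-positive cells.

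Signal also appeared outside the main measurement, as 13 hotspots on the mitochondrial chromosome. They fell in 4 libraries, with up to 4 in one, where a count of 0 allows up to 3.

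The first pattern weighed is the excess of lower over higher gene calls in mCherry+ cells, 480 against 216. The higher calls lay in surroundings with a median of 5 protein-coding genes within 500 kb and the lower calls with 16, against 15 for all genes. A gene density trend that differs between libraries was weighed as the whole cause. With the trend removed, the higher calls kept 92.07% of their median log2 change (0.66 ± 0.20 before, 0.61 ± 0.27 after) and the lower calls 87.6% (-0.79 ± 0.21 and -0.69 ± 0.21). This cannot decide the part of the trend, since the genes were picked for large changes in the same fit. Over all genes the median log2 change ran only from 0.12 where surrounding genes were fewest to -0.18 where they were most. Of the 216 higher and 480 lower calls, 110 and 208 stayed past the threshold, among 134 and 220 called after the removal. The others ended in part because the largest limma p that passed tightened from 0.00177 to 0.000893, since 152 and 291 would pass at the earlier limit. Scaling each library to its covered bases was weighed as the cause of the uneven numbers. With quantile normalization 46.7% of the calls were higher. This cannot decide the question, since that step gives all libraries one distribution and would even out a true difference as well. A true difference in gene-rich chromatin between the sorted populations stays open and was not tested.

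The second pattern is the excess of regions called in mCherry+ libraries alone, 541 against 59. List length was argued against, since at equal list lengths the ratio was 9.71, with 363 of the 505 mCherry+ regions shared with the full lists. The excess was present both in gene-dense (171 against 40, a ratio of 4.28) and in gene-poor surroundings (370 against 19, a ratio of 19.5). Its size differed with density, however, and one division at the median cannot show how much a density trend adds on either side. A part of such a trend in the excess therefore stays open. Cells on their way to become neurons among the mCherry+ cells, which the sort for the progenitor epitope CD15 should remove, are a candidate explanation: the pan-neuronal list was higher by mCherry (camera adjusted p = 3.16e-05, listed as 3.159e-05, and 0.0812 with an estimated correlation). Near the mCherry+ regions themselves, however, pan-neuronal genes stood at 5 of 541 against 32 of 7445 in the background (Fisher's exact adjusted p = 0.669), so this explanation stays open. Sequencing depth, which the files do not give, stays open.

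The third pattern is the height of Six3, Otx2, Vax1, Gsx2 and Fezf1 in Ascl1-single libraries, genes chosen after their values were seen. The lowest Ascl1-single library exceeded the highest other library for each, at 102.78 against 73.76 for Six3, 172.42 against 129.70 for Otx2, 61.21 against 52.58 for Vax1, 80.29 against 57.91 for Gsx2 and 118.40 against 83.38 for Fezf1. Cells of the ventral telencephalon, which the dissection of dorsal tissue should remove, could bring such regions into the GFP+ gate. The gabaergic list between Ascl1-single and double-negative cells gave a camera adjusted p of 0.00735 with the preset and 0.481 with the estimated correlation. Radial glia and housekeeping genes had the same 0.00735 with the preset, Notch pathway genes 0.0240 and pan-neuronal genes 0.0473, and all lost the threshold with the estimated correlation too (0.481, 0.444, 0.481 and 0.481), so the gabaergic list does not stand apart, and a mixture and a property of the Ascl1-single progenitors cannot be told apart on these 3 libraries. The number of lists called with the preset also depended on single libraries. It was 0 without double-negative replicate 3 and 9 without Ascl1-single replicate 2 or double-negative replicate 4.

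Other splits of the 12 libraries were used to ask whether chance alone gives counts as large. For the mCherry regions (600) and genes (696), chance was excluded: the real split alone of 100 reached its count, the highest others being 45 and 3. It was also excluded for regions private to Ascl1-single cells (322, 1 of 100, highest other 285) and double-positive cells (285, 1 of 100, highest other 280), as at equal list lengths (401, 1 of 100, highest other 202, and 433, 1 of 100, highest other 401). For double-negative cells few splits reached the count on the full lists (242, 4 of 100, highest other 285), but many did at equal list lengths (78, 22 of 100, highest other 401). The shares were not adjusted over the 4 groups, so chance is not excluded for double-negative cells. Over all 220 choices of 3 libraries, the full lists gave counts as large in 1, 2 and 7 cases for Ascl1-single, double-positive and double-negative cells, and the highest other was 322, that of the Ascl1-single libraries, for the latter 2. Chance was also not excluded for Neurog2-single cells (72, 64 of 100, highest other 280) or for GFP regions (23, 16 of 100), where the highest other, 600, is the mCherry split. A count of 0 is reached by every split and tells nothing, as for GFP genes (0, 100 of 100, highest other 4) and the interaction (0, 100 of 100, highest other 370), whose highest split places all 12 libraries by mCherry status.

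For gene lists, chance was not excluded for the number called by mCherry (4 lists, 22 of 100 splits, highest other 8) or by GFP (6 lists, 14 of 100, highest other 9). In the interaction 0 lists were called, which 100 of 100 splits reach by construction (highest other 10). By single list in the mCherry contrast, few splits reached the camera p of the pan-neuronal genes (3.72e-06, 1 of 100 splits, smallest other 4.81e-06). The same held for glutamatergic (1.01e-08, 3 of 100, smallest other 8.58e-09) and intermediate progenitor genes (4.33e-05, 3 of 100, smallest other 8.47e-07). These lists were picked because they passed camera, and the shares were not adjusted over the fixed lists. They therefore cannot exclude chance for a single list. With an estimated correlation the 3 lists did not pass (camera adjusted p = 0.0812, 0.138 and 0.270 in this order). For astrocyte genes chance was not excluded even without such adjustment (0.0113, 11 of 100, smallest other 0.000119).

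Pairs of groups allow 10 splits, too few for a share below 0.05. The real counts of genes and the highest others were 489 and 0 between double-positive and double-negative cells, 0 and 1 against Neurog2-single cells, 21 and 0 against Ascl1-single cells, 1 and 0 between Neurog2-single and Ascl1-single cells, 7 and 0 between Neurog2-single and double-negative cells, and 0 and 1 between Ascl1-single and double-negative cells. Of the 10 splits, 1, 10, 1, 1, 1 and 10 reached the real count in this order. For lists between double-positive and double-negative cells, 4 of 10 splits reached the 3 lists called, the highest other being 9.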

How the results depend on the processing

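The tests with both longest lists left out, gene ends with 1 kb, gene density removed, gene families, list enrichment, similarity by reporter, splits of group regions at equal list lengths or over all choices, and footprint lists of equal length were chosen only after the results were seen. Of the alternatives to results that answer a comparison, 407 kept their side of the threshold or stayed within 1.5 times, 163 moved, 6 passed the threshold and 5 lost it. A change of direction was counted only where the main or the alternative result passed the threshold. Of those for single genes and lists, 6829 were the same, 996 lost the threshold, 141 gained it and 8 reversed. Unless the construction shows it, the cause was not tested.

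All 8 reversals came with another assignment of regions to genes: with gene ends, Neurod4 by mCherry (-0.0859, limma adjusted p = 0.917), Zc2hc1b by mCherry (-0.0039) and between double-positive and double-negative cells (-0.0077), Mboat7 between Neurog2-single and double-negative cells (0.13), Notch2 by mCherry (0.0403), and Cux1 (0.0489) and Pdgfrb (0.15) between double-positive and double-negative cells; with the gene body and 10 kb, Aldob by mCherry (-0.21). None of these 8 came from scaling, while a change of sign between values past no threshold was not counted as a reversal.

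Called regions changed with their definition. With 50% of the region covered, mCherry+ regions numbered 251, GFP− 2 and double-positive 492. In 500 bp bins there were 1027 mCherry+, 126 mCherry−, 30 GFP+, 566 double-negative, 644 Ascl1-single, 178 Neurog2-single and 596 double-positive. At equal list lengths there were 20 GFP+, 2 GFP−, 78 double-negative, 37 Neurog2-single and 433 double-positive. With both longest lists left out, fewer libraries have to agree, and there were 883 mCherry+, 230 mCherry−, 53 GFP+, 64 GFP−, 1759 double-negative, 552 Ascl1-single, 661 Neurog2-single and 539 double-positive.

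Numbers of called genes moved by mCherry to 29 with gene ends, 29 when regions were counted instead of bases, 225 with both longest lists left out and 354 with gene density removed. Between double-positive and double-negative cells they moved to 14 with gene ends, 26 with regions counted, 134 with both longest lists left out, 323 with density removed, 246 with quantile normalization and 290 at equal list lengths. Between double-positive and Ascl1-single cells they were 0, 6 and 6 under the first 3 of these, 2 at equal list lengths, 294 with array weights, 53 for genes covered in all 12 libraries and 55 with the gene body and 10 kb. Between Neurog2-single and Ascl1-single cells they were 0 with quantile normalization, equal list lengths, regions counted, both longest lists left out or density removed, 2 for genes covered in all 12 or with the gene body, and 3 with array weights or a pseudocount of 50. Between Neurog2-single and double-negative cells they were 0 with gene ends, regions counted or the gene body, 1 with a pseudocount of 1, genes covered in all 12, equal list lengths, both longest lists left out or density removed, and 11 with a pseudocount of 50. Between Ascl1-single and double-negative cells, 1 gene passed without the filter or with both longest lists left out.

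Of 153 list tests, 40 passed with camera, 12 with regions counted, 17 with gene ends, 16 with fry and 0 with an estimated correlation. Footprints in no other group were 24.4% in Ascl1-single and 26.6% in Neurog2-single cells with an overlap of 1 bp, and 19.1%, 21.2%, 24.0% and 37.9% in double-negative, Ascl1-single, Neurog2-single and double-positive cells for the stronger part of each list. With lists of equal length they were 37.7% in double-negative, 23.8% in Neurog2-single and 27.7% in double-positive cells. By fold over background in the authors' deposited tables, the leading motif of Neurog2-single cells ranked 27 and that of double-positive cells 10.

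Leaving out each library in turn, results ranged as follows. The GFP difference in hotspot number went from -43026.3 to -24446.5, similarity by group from 0.00765 to 0.0337 and by replicate number from -0.0028 to 0.0194. The mCherry difference in hotspot number changed sign, from negative with all libraries to positive without double-negative replicate 3. Regions ranged from 68 to 156 for mCherry−, 13 to 37 for GFP+ and 16 to 32 for GFP−. They ranged from 260 to 2697 for double-negative, 338 to 1290 for Ascl1-single, 80 to 1255 for Neurog2-single and 302 to 1034 for double-positive, where a group short of one library has fewer lists to agree. Called genes ranged from 208 to 901 by mCherry, 36 to 681 between double-positive and double-negative cells, 0 to 110 between double-positive and Ascl1-single cells, 0 to 2 between the single groups, 0 to 13 between Neurog2-single and double-negative cells and 0 to 1 between Ascl1-single and double-negative cells.

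In 4 of the 6 comparisons of groups the replicate numbers were not read as pairs, as not all 3 same-numbered pairs correlated above 0.1. Pairing is not ruled out there. Same-numbered pairs had correlations of their deviations from 0.0126 to 0.222, with 10 of 18 over 0.1. Their mean was 0.107, against -0.053 for different numbers. In addition, 11 of 12 libraries correlated best with one of their own number, a hint from the data and not the design. With the replicate number as a block, 1183 genes were called by mCherry, 1019 between double-positive and double-negative cells, 290 between double-positive and Ascl1-single cells and 20 between Neurog2-single and double-negative cells, including all 696, 489 and 21 of the first 3 contrasts. Between Neurog2-single cells and double-positive or double-negative cells, where the numbers were read as pairs, the block changed no other call.

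Depth limits the regions, since the lists give no coverage. Counts of sequence words, and genes assigned by promoter or nearest start site, were not run, for want of a genome and of strand.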

Other observations

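The look at gene families was chosen only after the results were seen.

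Families of receptor, keratin-associated protein and defensin genes lie outside the fixed lists. The 967 olfactory and vomeronasal receptor genes had a median log2 difference of 0.04 by mCherry, with 5 higher and 1 lower; it was 0.14 with quantile normalization, which moved the median of all genes by 0.09, and 0.19 with the gene density trend removed. Between double-positive and double-negative cells their median was -0.09, and 0.11 with quantile normalization, which moved the median of all genes likewise, from -0.107 by 0.134. Keratin-associated protein genes (32) had a median of 0.03 by mCherry with 3 higher, and beta defensin genes (28) one of 0.06 with 0 past limma's threshold.

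Libraries of the same replicate number had a Jaccard difference of 0.0079 (one-sided exact permutation p = 0.0871 over 5775 sets). By the same exact permutation test it passed without Ascl1-single replicate 3 (0.0194, p = 0.0194), double-positive replicate 2 (0.0177, p = 0.0168) or double-positive replicate 3 (0.0176, p = 0.0239).

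Of the footprints, 99.3% to 99.9% lay in regions called in all 12 libraries, and 347 to 354 per group were found in all groups. Those inside a gene made up 35.3% in double-negative, 38.8% in Ascl1-single, 42.0% in Neurog2-single and 43.3% in double-positive cells. Of 32 bHLH motifs in the authors' deposited tables, 8 passed in double-negative, 11 in Ascl1-single, 11 in Neurog2-single and 13 in double-positive cells, without allowance for the different lengths of the footprint lists. These counts do not stand for proneural motifs. Ascl1, Atoh1 and Tcf12 passed in no group, and NeuroD1 and Olig2 passed in neither Ascl1-single nor Neurog2-single cells. The best-ranked bHLH motif of Neurog2-single cells, at rank 22, was Usf2.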
